A study of Homo sapiens with 29 samples.

How the data were processed

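The data are circular RNA (circRNA) isoform tables from 29 sequencing libraries in 11 groups. Circular RNAs are closed rings in which a downstream splice site is joined to an upstream one (a back-splice). RNA came from human brain, from the human embryonic kidney line HEK293, from non-small cell lung cancer (NSCLC) tumour, and from healthy and NSCLC blood plasma. Brain and tumour RNA was commercially obtained, HEK293 RNA was prepared with a total RNA miniprep kit and plasma RNA with a cell-free RNA kit, per the labels. Brain and HEK293 RNA was used either as total RNA or after removal of ribosomal RNA followed by RNase R, an exonuclease that digests linear RNA. These treated libraries are called RNase R libraries here, and their 2 steps were always applied together. All libraries were made by rolling reverse transcription with a group II intron reverse transcriptase (Induro), bead size selection of the cDNA, Phi29 second strand synthesis and amplification, and T7 endonuclease I debranching, and were sequenced on Nanopore or PacBio instruments. Of the 11 groups, 9 have 3 libraries and both plasma groups have 1. Nothing in the labels says that the replicates of a group came from separate donors or cultures, so p-values measure only the spread between these libraries, which may be technical.

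The values are expected counts of reads per circRNA isoform, as deposited and per the file headers. Reads were aligned with minimap2 to GRCh38/hg38, per the submitters' processing notes. The circRNA caller and its filters, and how isoforms were matched across libraries, are not given in the sources used here. Each isoform was listed by chromosome, start, end and exon chain, with no strand and no gene name, so overlapping genes on opposite strands could not be told apart. Libraries were listed in 1 to 43 columns of read subsets, which were summed. The 2 libraries with 1 column were replicate 1 of brain total RNA on Nanopore and on PacBio, and neither held a circRNA at 1 read. A further 3 libraries lacked 1 number in their series of subsets. All 29 libraries held some values that were not whole; at the lowest, 83.8% of the values above 0 were whole. Sums were rounded to whole numbers for the count models. A circRNA here is 1 back-splice (chromosome, start and end) with the counts of its isoforms summed. The tables held 1297401 isoforms and 1091539 back-splices. Total reads ranged from 48256 to 3386583 in the 27 replicated libraries and were 44625 in healthy plasma and 18392 in NSCLC plasma. All 29 libraries had fewer circRNAs at 1 read than at 2 reads. Counts were of reads without molecular identifiers, so intervals and floors cover counting error only.

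Back-splices were assigned to genes with the GENCODE version 29 annotation. A back-splice had a host gene when exons of exactly 1 annotated gene held both of its ends, which gave a host gene to 84.8% of the human reads. A further 8918 back-splices, with 1.69% of reads, had more than 1 gene and no host. Both ends on annotated exon ends of 1 gene defined the exon-end class, the pattern of canonical back-splicing; the other classes were inside exons, mixed exon and intron, inside introns of 1 gene, across genes or a gene edge, and intergenic. Counts of all circRNAs of a host gene were summed for the host gene tests; circRNAs inside introns or with 1 end in an intron have no host gene here. Spike-in contigs in the NSCLC libraries were left out of all tests. Genes of the Y chromosome and XIST were left out of all tests.

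Differences in circRNAs and host genes were tested with edgeR 4.0.16 (quasi-likelihood, two-sided) in R 4.3.3 with the data.table package (version 1.17.8), with TMM scaling and filterByExpr by group, and Benjamini-Hochberg adjusted p under 0.05. PacBio circRNAs (35978 tested) and host genes (6669 tested) were fitted over the 15 replicated PacBio libraries, Nanopore circRNAs (10685 tested) over the 12 Nanopore libraries, and the platform comparison (16597 tested) over the 24 brain and HEK293 libraries, as the mean of PacBio against Nanopore over the 4 pairs of tissue and preparation. The interaction tested whether the RNase R effect differed between brain and HEK293. Isoform usage within circRNAs was tested with edgeR diffSpliceDGE (Simes p per circRNA) over 6 libraries, with isoforms of at least 10 counts. Folds against a group in which all libraries were at 0 are given as at least N-fold, against a floor of 3 counts over the group; with 1 to 3 counts the ratio is given with a 95% counting interval. CPM is the edgeR cpm value with TMM-scaled library sizes, and values are mean ± SD with n = 3 unless said otherwise. Library measures were compared by exact permutation of labels within strata (160000 arrangements, two-sided), adjusted over 7 measures: the number of distinct circRNAs after thinning each library to 47758 reads, read-weighted median length, and the percentages of reads in circRNAs of 1000 nt or longer, in isoforms of 2 or more exons, on annotated exon ends, in the 10 most abundant circRNAs and on the mitochondrial genome. The number of distinct circRNAs is not compared in the results, because the caller had filtered each library at its own depth before the thinning. With 3 against 3 libraries an exact test within 1 stratum cannot go below p = 0.1. Plasma shares carry exact (Clopper-Pearson) binomial 95% intervals from scipy 1.17.1 and were not tested between libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots, and the random seed was 7.

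The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. Named host genes were the 10 with the largest and the 10 with the smallest log2 fold change among those with adjusted p under 0.05, a mean log2 CPM of at least 5 and every library of one group above every library of the other, and up to 4 members of each list with the smallest adjusted p. By the same rule the 5 highest and the 5 lowest circRNAs were named per circRNA comparison, the 3 highest and the 3 lowest for the interaction, and the 5 with the smallest adjusted p for isoform usage. For plasma the rule named the 5 host genes with the most counts per library and the 5 highest and the 5 lowest ratios among genes with at least 10 counts in 1 library. The 20 lists were presynaptic active zone and vesicle release, postsynaptic density and receptors, neuronal ion channels, oligodendrocyte and myelin, astrocyte, microglia and macrophage, lymphocyte, endothelial, fibroblast and extracellular matrix, lung epithelium, epithelial and squamous, cell cycle, mitochondrially encoded, cytosolic ribosomal proteins, structural noncoding RNAs, long nuclear or abundant linear transcripts, commonly reported circRNA hosts, erythroid, platelet and megakaryocyte, and neutrophil. Lists were tested with limma 3.58.1 camera (preset correlation 0.01), adjusted over 75 tests in 5 comparisons, and by counting members past the threshold, adjusted over all genes and over the list alone. SHANK3 is a member of both the postsynaptic and the endothelial list.

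The tests were tried on simulated data made from these libraries. Apart from 200 planted changes per trial, each simulated feature had the same level in all groups. Groups of different composition were thus not simulated, and the shares of false calls do not cover errors of scaling between them. For the circRNA fit over the PacBio libraries (35978 circRNAs), 3.03%, 19.4% and 48.4% of changes planted at 2-, 4- and 8-fold in brain against HEK293 were called, and 6.12% of calls were false. For the interaction the shares were 0%, 9.38% and 18.6%, with 9.52% false calls. For the Nanopore fit (10685 circRNAs) they were 4.17%, 45.6% and 76.1%, with 4.60% false calls, and for the platform comparison (16597 circRNAs) 49.0%, 88.9% and 96.1%, with 6.32%. For host genes (6669) they were 14.5%, 66.7% and 79.0%, with 5.41% false calls. The isoform usage test called 85% of 200 planted changes among 3666 circRNAs, with 2.86% false calls. In this trial the spread was a fixed value, not taken from the libraries. Changes were planted as swaps of the 2 most read isoforms, only in circles with many expected reads and a dominant isoform. Both shares therefore do not carry over to the test on the real libraries. Camera found the 1 planted list and 0 of 20 unplanted ones. Genes were simulated independently of each other, so correlation within a list was not tried.

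Alternatives set before the data were examined were median-ratio size factors from DESeq2 (RLE) in edgeR, total counts only, the DESeq2 1.42.0 Wald test, a minimum of 3 counts in place of the filter for circRNAs and no filter for host genes, a fit of only the groups compared, the replicate number as a block, leaving out each replicate, only circRNAs on exon ends, and mitochondrial circRNAs left out. For isoform usage they were at least 30 counts per isoform and a gene-level F test; for library measures and plasma, circRNAs weighted once or with at least 2 reads; and for the lists, an estimated correlation in camera. Alternatives chosen after seeing the data were only circRNAs of mean log2 CPM of 5 or more, the lists recounted from circRNAs on exon ends alone, and the permutation of library measures with same-numbered libraries of both platforms moved together.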

Results

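To compare circular RNAs read at full length, the libraries from brain, HEK293 and NSCLC tumour were tested group against group, and the 2 plasma libraries were described as single measurements. Brain libraries held 435707 to 3386583 reads and HEK293 libraries 48256 to 2636273. NSCLC tumour libraries held 308863 to 785219, of which 140477 to 365113 were human, and the depth of each comparison limited which circRNAs could be tested. Unless a value is given, a gene was called by edgeR at adjusted p under 0.05. Every circRNA or host gene named for its fold between 2 groups had all 3 libraries of one group above all 3 of the other. Chance gives such a separation to 10% of items. Circles named for the interaction are not covered by this statement.

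The treatment with ribosomal RNA removal and RNase R took away long circRNAs in HEK293. The 3885-nt circRNA of ARHGAP5, which encodes a signalling regulator (chromosome 14, 32090502 to 32094386), fell from 27213.5 ± 714 CPM to 0 in 3 treated PacBio libraries, at least 63123-fold lower. A second ARHGAP5 circRNA of 4033 nt (32090502 to 32117287) fell from 13732 ± 504 CPM to 0, at least 31851.5-fold lower. Circles of ARGLU1, a splicing cofactor (2610 nt, at least 4432-fold), of CASP8AP2, a histone gene regulator (5476 nt, at least 2689.6-fold), and 1 inside exons of HNRNPK, an RNA-binding protein (1248 nt, at least 6581-fold), were also lost. The largest gains were shorter circles of the receptor IGF2R (615 nt, 133 ± 4.34 CPM from 0, at least 57.2-fold), the hypoxia factor HIF1A (738 nt, at least 33.1-fold), the microtubule-severing enzyme KATNA1 (514 nt, at least 32.3-fold), the kinase STK3 (333 nt, at least 31.5-fold) and the fucosyltransferase FUT8 (430 nt, at least 31.2-fold). Of 35978 circRNAs tested with edgeR, 8979 were higher and 6093 lower after treatment. With TMM 59.6% of calls were higher and with RLE scaling 43.6%, which shifted the median by -0.59 (log2), so the split depends on the scaling.

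In brain the same treatment removed a 2461-nt circRNA of RTN4, an inhibitor of neurite growth (chromosome 2, 55025086 to 55028220), from 8023 ± 1178 CPM to 0, at least 11793-fold lower. Both ARHGAP5 circRNAs were lost here too, the 4033-nt one from 3857 ± 849 CPM (at least 5669.9-fold) and the 3885-nt one from 1192 ± 222 CPM (at least 1752-fold). Circles of the SUMO protease SENP6 (1525 nt, at least 1839-fold) and of QSER1, a DNA methylation regulator (3968 nt, at least 1557-fold), followed. The largest gains were circles of PCID2, of the mRNA export complex (429 nt, 271 ± 39.3 CPM from 0, at least 361-fold), and of the ubiquitin ligase subunit FBXO9 (312 nt, at least 250.2-fold). The microtubule-binding CLIP1 (763 nt) gained 556-fold (counting interval 154 to 4599), the GABA transaminase ABAT (296 nt) 368-fold (101.5 to 3043) and the kinase STK39 (256 nt) 233-fold. Of 35978 circRNAs tested with edgeR, 9778 were higher and 11105 lower. Higher calls made up 46.8% with TMM and 61.8% with RLE scaling, which shifted the median by 0.90 (log2).

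Nanopore libraries gave the same kind of loss, with 10685 circRNAs tested. In HEK293 4390 were higher and 1066 lower (2991 to 5491 calls with 1 library left out), and the ARHGAP5 circles of 3885 nt (16144 ± 967 CPM, at least 5758-fold) and 4033 nt (at least 2858-fold), those of ZNF644 (3705 nt) and ARGLU1 (2610 nt) and 1 inside exons of HNRNPK (1253 nt) fell to 0. ERC1, a presynaptic scaffold gene (825 nt, at least 60.1-fold), SMAD2, a TGF-beta effector (783 nt, at least 42.7-fold), and CAMSAP1, NSD2 and TCFL5 gained. In brain 2664 were higher and 4421 lower, and circles of RTN4 (2461 nt, at least 2698-fold), TULP4 (2334 and 2218 nt), SENP6 (1722 nt) and the bicarbonate transporter SLC4A7 (2552 nt) fell to 0. PCID2 (429 nt, at least 67.8-fold), ABAT, CLIP1, C9orf3 and a circRNA with no host gene on chromosome 7, 32722723 to 32726470, gained. Of the Nanopore calls 80.5% were higher in HEK293 (46.3% with RLE, median shift -1.09, and 61.9% with total counts) and 37.6% in brain (58.2% with RLE, median shift 1.24).

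By length, the loss was found in both tissues and on both platforms. Among PacBio circRNAs of 2000 nt or longer, 2481 of 3189 were lower and 12 higher in brain, and 2718 of 3427 were lower and 17 higher in HEK293. On Nanopore 533 of 602 were lower in brain and 436 of 570 in HEK293. This direction held with TMM, RLE and total-count scaling. In brain with PacBio, 5269 of 6576 circRNAs from 300 to under 500 nt were higher, a majority under each scaling, whereas the class from 500 to under 1000 nt had 24.4% higher and 19.1% lower and its direction changed with total counts (2610 higher, 2941 lower). In HEK293 with PacBio, 5514 of 12520 circRNAs from 500 to under 1000 nt were higher and 4.49% lower, and circles under 300 nt did not lean to 1 side (15.1% higher, 17.04% lower). Circles of 2000 nt or longer held 13.6 ± 0.186% of brain PacBio reads in total RNA and 0.0658 ± 0.052% after treatment, and in HEK293 39.03 ± 0.602% and 1.27 ± 0.249% (n = 3 each).

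**Figure D1:**
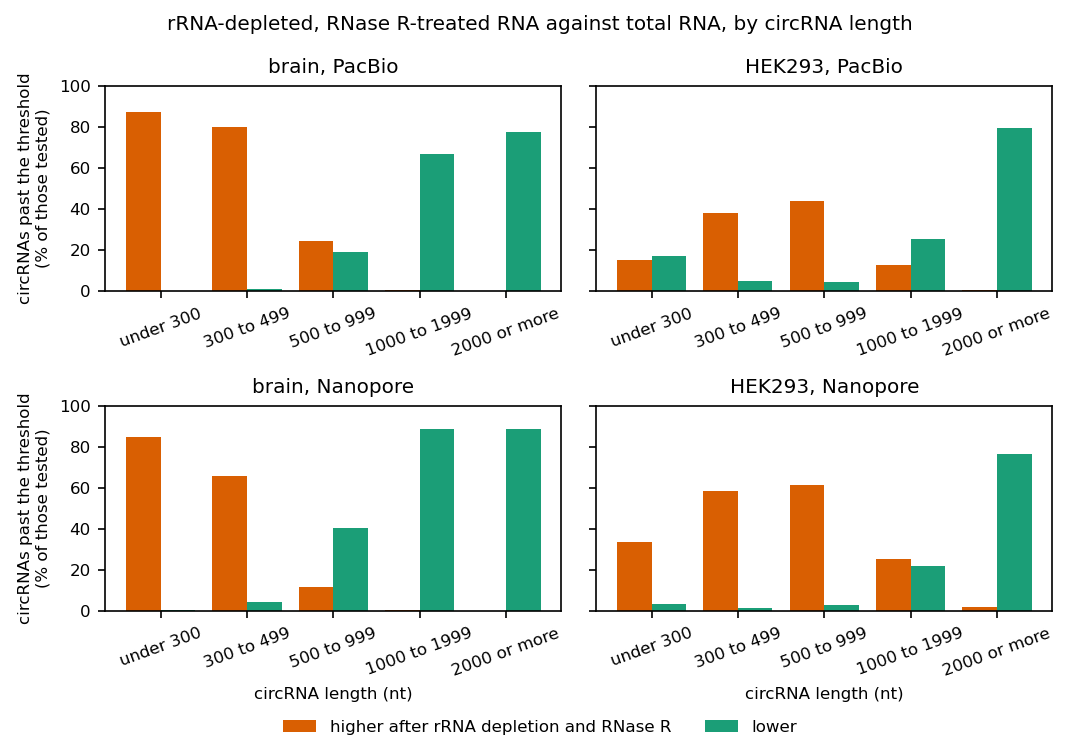
Percent of tested circRNAs (y axis) in each length class (x axis, nt) that passed the edgeR threshold as higher (orange) or lower (green) after ribosomal RNA removal and RNase R, in 4 panels by tissue and platform. At 2000 nt or longer 77.8% were lower in brain and 79.3% in HEK293 with PacBio.

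Over the 24 brain and HEK293 libraries, the read-weighted median length fell by 672 nt with treatment (603.5 nt against 1275.7 nt) and the reads in circRNAs of 1000 nt or longer fell by 46.8 percentage points. Reads in isoforms of 2 or more exons rose by 16.5 points and reads on annotated exon ends by 10.4 points. Each of these differences had this direction in 4 of 4 strata (exact permutation, adjusted p = 2.1875e-05, from a p of 1.25e-05, the smallest that 160000 arrangements can give). That p takes all 24 libraries as separate. With libraries of the same number on both platforms moved together, a choice made after seeing the data, it is 0.00875 (exact permutation, adjusted, from 0.005, the smallest that 400 arrangements can give). The share of the 10 most abundant circRNAs (-2.10 points, exact permutation, adjusted p = 0.103) and the mitochondrial share (adjusted p = 0.66) did not pass. The treated libraries had lost both ribosomal RNA and linear RNA, so the 2 steps cannot be told apart.

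**Figure D2:**
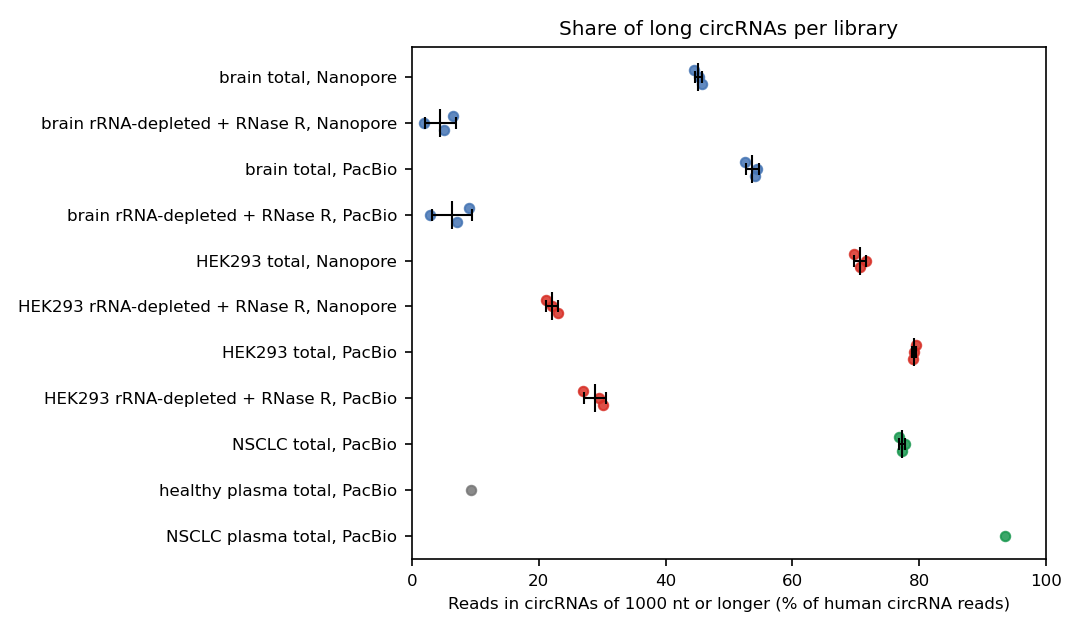
Percent of human circRNA reads in circRNAs of 1000 nt or longer (x axis) in each of 11 groups (y axis). Dots are libraries and the tick and bar are mean ± SD (n = 3; plasma n = 1); brain PacBio was 53.7 ± 0.994% in total RNA and 6.33 ± 3.21% after RNase R, HEK293 79.2 ± 0.265% and 28.9 ± 1.67%.

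Well-studied circRNAs were matched here as the most read circle of each listed host gene, a choice made after seeing the data. The 1099-nt circle of the kinase HIPK3 (chromosome 11, 33286413 to 33287511) rose in HEK293 from 673 ± 75.2 to 3857 ± 71.1 CPM (log2 2.52, adjusted p = 1.54e-05 by edgeR) and did not pass in brain (-0.59, adjusted p = 0.121). The 2218-nt circle of TULP4 fell from 6010 ± 231 to 0.921 CPM in brain (log2 -12.53) and to 72.0 CPM in HEK293 (-7.42). Circles of the signalling adaptor CRKL (466 nt, log2 4.41 in brain) and the focal adhesion kinase PTK2 (493 nt, 1432 to 7578 CPM in brain) rose, and those of the clathrin assembly gene PICALM (1278 nt, log2 -6.14) and of UBAP2 (1587 nt, -5.57) fell. Short circles of ASXL1 (196 nt, 3.75 in brain, -1.98 in HEK293), FBXW7 (308 nt, 4.06 and -3.39) and CORO1C (395 nt, 2.74 and -1.58) moved in opposite directions in the tissues.

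At the level of host genes, treatment changed the balance of circles between genes. Counted from all circles, no gene list passed the threshold of the test. With edgeR 2072 of 6669 host genes were higher and 1620 lower in brain, and 1826 were higher and 1145 lower in HEK293. Among 21 ion channel genes 13 were higher and 4 lower in brain (limma camera adjusted p = 0.136), and of 26 cell cycle genes 2 were higher and 9 lower in brain (0.074) and 5 higher and 7 lower in HEK293 (0.14). Of 31 commonly reported hosts 15 were higher and 10 lower in brain and 15 higher and 11 lower in HEK293. No list passed in either tissue with camera (0 of 30 tests; 2 in brain and 0 in HEK293 at unadjusted p under 0.05). The sign of the astrocyte median in brain (-0.41) changed with RLE (0.18) and that of the cell cycle median in HEK293 (-0.16) with total counts (0.04). From exon-end circles alone, a choice made after seeing the data, cell cycle genes were called lower in HEK293 (camera adjusted p = 0.0497). There 5 of 24 were higher and 8 lower. In brain they did not pass (camera adjusted p = 0.054).

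The size of the treatment effect differed between brain and HEK293 for individual circRNAs. A 338-nt circle of RANBP17, an importin relative (chromosome 5, 171183195 to 171205612), rose from 311 ± 55.5 to 4259 ± 441 CPM in brain and fell from 36.55 ± 37.02 to 0 in HEK293 (interaction log2 12.12, adjusted p = 9.594e-06). A 493-nt circle of the Polycomb gene SFMBT2 (chromosome 10, 7243558 to 7285954) rose from 166 ± 48.1 to 1190 ± 48.0 CPM in brain and fell from 43.3 ± 13.3 to 0 in HEK293 (11.47). The 7635-nt circle of TNRC6A, a microRNA effector, was read in total HEK293 only (459 ± 95.9 CPM, 12.56). Long circles of SLC4A7 (2444 nt, -17.60, adjusted p = 0.0488), SDCCAG8 (1922 nt, -13.65) and the transporter ABCA5 (2457 nt, -13.26) were read in total brain (1409 ± 1220, 183 ± 100.3 and 142 ± 23.9 CPM) and were at 0 in treated brain. For these 4 circles the other tissue held no more than 1.51 CPM in both preparations, so their values show the loss in 1 tissue. The SD of the SLC4A7 circle was close to its mean, so its level varied widely between the total brain libraries. The edgeR interaction test called 7186 of 35978 circRNAs, 1149 higher and 6037 lower in brain relative to HEK293 (11893 at unadjusted p under 0.05, and 5117 to 13881 calls with 1 library left out). Higher calls made up 16.0% with TMM and 68.7% with RLE (2612 called), which shifted the median by 1.16, so neither direction holds across scalings.

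Brain and HEK293 differed in the genes from which circles arose. Circles of NTRK2, the BDNF receptor, reached 4987 ± 739 CPM in brain and 0 in HEK293 (at least 1611-fold). Those of CSMD3 (at least 792-fold), the lipid kinase DGKB (727-fold), the bicarbonate transporter SLC4A10 (529-fold), the lipoprotein receptor LRP1B (509-fold), the lyase HMGCLL1 (434.5-fold), the astrocytic glutamate transporter SLC1A2 (409.7-fold), the active-zone scaffold RIMS1 (344-fold), the vesicle-priming gene UNC13C (334-fold) and the relaxin receptor RXFP1 (278-fold) were also at 0 in HEK293, each fold a lower bound. In HEK293 circles of cell division genes prevailed: ASPM, a spindle protein (1139 ± 43 CPM, 2702-fold, interval 746 to 22337), NCAPG of condensin (at least 312-fold), TOP2A, a topoisomerase (at least 266-fold), KIF23 (at least 136-fold) and KIF14 (476-fold, 130.1 to 3962), both kinesins of cytokinesis, and CDCA2 (at least 77.7-fold). The chemokine CXCL8 (1181-fold, 325 to 9783), the repair gene BRCA2 (553 ± 100.2 CPM, log2 -9.22) and the ion channels MCOLN2 (at least 62.8-fold) and MCOLN3 (at least 84.1-fold) completed the genes with the largest changes. Of these, SLC1A2 in brain (12 of 5858 reads) and CXCL8 in HEK293 (0 of 481) lay almost wholly off exon ends. With edgeR 2138 of 6669 host genes were higher in brain and 1480 lower.

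Gene lists of the nervous system were higher in brain. Of 20 presynaptic genes 18 were higher and 0 lower (18 adjusted over the list alone), with CADPS2 (log2 7.65) and STXBP5L (4.34) as further examples, and the median was 6.58, or 4.61 with genes at 0 counts set to their bound (camera adjusted p = 3.002e-08). Of 20 postsynaptic genes 18 were higher (19 over the list alone), among them the glutamate receptor GRIA2 (at least 92.7-fold, 13.6% of reads on exon ends, median 8.40, 3.36 at the bound, adjusted p = 1.799e-05). Of 21 ion channel genes 18 were higher (18 over the list alone), led by the sodium leak channel NALCN (7654 ± 461 against 33.0 ± 12.3 CPM, log2 7.85, list median 7.85, 3.71 at the bound, 1.799e-05). Of 10 astrocyte genes 8 were higher and 1 lower (9 and 1 over the list alone, AQP4 at least 128-fold with 0 of 1816 reads on exon ends, median 7.48, 4.83 at the bound, 0.0003909), and of 12 oligodendrocyte genes 9 were higher (11 over the list alone, median 5.55, 2.24 at the bound, 0.006742). Of 26 cell cycle genes 20 were lower and 0 higher (20 over the list alone, SMC4 log2 -5.43, list median -4.89, -4.33 at the bound, 1.415e-10). With an estimated correlation only the cell cycle list passed (adjusted p = 0.001001). The presynaptic, postsynaptic, astrocyte and oligodendrocyte lists had adjusted p = 0.0649 and ion channels 0.1569. These directions held under each scaling. From exon-end circles alone, a choice made after seeing the data, the astrocyte (adjusted p = 0.305 by camera) and oligodendrocyte (0.334) calls were lost.

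The other lists did not pass between brain and HEK293. Commonly reported hosts had 14 of 31 higher and 4 lower (adjusted p = 0.345 by camera), with PTK2 (log2 3.20) and PICALM (2.13) higher and the exportin XPO1 (-2.02) lower. Macrophage genes had 3 of 7 higher (2 over the list alone; 0.771), endothelial genes 2 of 5 (1 over the list alone; 0.524), lung epithelium genes 2 of 3 (0.524), and fibroblast genes 2 higher and 3 lower of 13 (0.771). Lymphocyte genes had 1 of 7 lower (BACH2, -3.43; 0.80), epithelial genes 1 of 4 lower (0.524), long nuclear or abundant transcripts 3 higher and 1 lower of 8 (NEAT1, -4.62; 0.771) and ribosomal proteins 0 of 5 (0.57). Erythroid, neutrophil and platelet genes, with 2, 2 and 1 measured, each had 1 lower. No mitochondrially encoded gene or structural noncoding RNA was measured (0 each). For fibroblast, lymphocyte and long transcript genes the sign of the median differed from that of the test.

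Among single circRNAs, the most raised in brain with PacBio were circles of SLC4A7 (2552 nt, chromosome 3, 27379249 to 27424152, 4718 ± 552 CPM, at least 2029-fold) and NTRK2 (371 nt, at least 1395-fold). Next was the 1485-nt circle of LINC00632 (chromosome X, 140783175 to 140784659, 2918 ± 566 CPM, at least 1255-fold), which encloses the annotated gene CDR1, followed by circles of ATRNL1 (473 nt, at least 988-fold) and the adhesion receptor ADGRB3 (551 nt, at least 838-fold). In HEK293 the most raised were the HNRNPK circle inside exons (2837 ± 89.3 CPM, at least 3788-fold), 1 with no host gene on chromosome 2, 135753539 to 135755464 (at least 1397-fold), and circles of SKIL, SUCO and TNRC6A. With edgeR 13530 of 35978 were higher in brain and 5640 lower on PacBio, and 6072 and 826 of 10685 on Nanopore (4118 to 7365 calls there with 1 library left out). On Nanopore the potassium channel KCNN2 (419 nt, at least 499.1-fold), NALCN (838 nt, at least 443-fold), SLC4A7 and ATRNL1 led in brain. DNAH14, SREK1, TMEM67, the circle on chromosome 2 (at least 214-fold) and 1 on chromosome X, 115707404 to 115713206, led in HEK293. The share of higher calls was 70.6% on PacBio (55.5% with RLE, median shift -0.78, and 56.9% with total counts) and 88.0% on Nanopore (67.9% with RLE, median shift -1.10, and 60.2% with total counts).

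Brain circles were shorter than those of HEK293. Median length fell by 422 nt in brain (728.5 against 1150.7 nt), and reads in circRNAs of 1000 nt or longer fell by 22.8 points. Reads in isoforms of 2 or more exons were 10.4 points higher and reads on exon ends 5.97 points higher. Each held in 4 of 4 strata (exact permutation, adjusted p = 2.1875e-05, from the smallest p possible, or 0.007 with same-numbered libraries moved together). When each circRNA counted once, the exon-end difference was 0.926 points (exact permutation, adjusted p = 0.507) and that of isoforms of 2 or more exons 4.25 points (0.00365). The mitochondrial share was 0.000157 points higher in brain (exact permutation, adjusted p = 0.0056, 3 of 4 strata) but did not pass without replicate 3 in every group (0.117). It rests on few reads, 7 of mitochondrially encoded genes over the 3 brain total PacBio libraries. The share of the 10 most abundant (-0.717 points, adjusted p = 0.613) did not pass.

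Among the host genes with the largest rise in NSCLC tumour over HEK293 were genes of immune cells and of the matrix. Circles of SCN7A, a sodium channel gene, reached 1438 ± 149 CPM and 0 in HEK293 (at least 464.5-fold), and 97.5% of them lay on exon ends. Lysozyme LYZ (1328 ± 300 CPM, at least 429-fold), the phagocyte oxidase CYBB (at least 301-fold), collagens COL1A2 (at least 274-fold) and COL3A1 (at least 97.6-fold), the signalling adaptors PIK3AP1 (at least 250.1-fold) and FYB1 (at least 131-fold), and the cholesterol exporter ABCA1 (at least 148-fold) had 0 reads on exon ends: all lay inside exons. The carboxypeptidase gene CPM (at least 118-fold) had 19.1% and MACC1, a MET regulator (at least 111.5-fold), 83.3% of reads on exon ends. The most read tumour circle was seen in only 1 of 3 libraries for CYBB, COL1A2, PIK3AP1 and ABCA1 and in 2 for LYZ and FYB1. For COL3A1, CPM and MACC1 it was seen in all 3. Lower were circles of the synaptotagmin SYT14 (352 ± 85.2 CPM to 0, at least 78.6-fold), ANKRD18B (69.9-fold), the amino acid transporter SLC6A15 (63.6-fold), the sulfotransferase NDST4 (55.3-fold), the formin FMN2 (47.0-fold), the adaptor GRB10 (37.9-fold), GPR137C (30.9-fold), SYTL5 (30.35-fold), the kinase MARK1 (28.1-fold) and the ciliary gene INVS (27.55-fold), each a lower bound. With edgeR 813 of 6669 host genes were higher and 1617 lower. Among these calls 33.5% were higher with TMM, 53.6% with RLE and 57.3% with total counts, which shifted the median by 0.66 and 0.77, so the balance of directions depends on scaling.

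Against HEK293, 6 of 7 macrophage genes were higher (6 over the list alone, camera adjusted p = 3.583e-05, median 6.89, 4.38 at the bound), and 8 of 13 fibroblast genes were higher and 1 lower (9 and 1 over the list alone, 3.583e-05, median 3.84, 3.23 at the bound), as FN1 (2.48) and SPARC (at least 66.99-fold). All 3 lung epithelium genes measured were higher: the kinase ROS1 (205 ± 4.75 CPM, at least 66.1-fold), LAMP3 (at least 13.02-fold) and HOPX (7 counts, at least 2.61-fold), with 3 over the list alone (adjusted p = 0.04169). On exon ends lay 126 of 137 tumour reads of ROS1, 0 of 27 of LAMP3 and 0 of 7 of HOPX. Of 26 cell cycle genes 19 were lower and 0 higher (21 over the list alone, camera adjusted p = 4.505e-08, median -3.61, -2.95 at the bound), as KIF11 (log2 -5.30) and POLA1 (-3.61). Commonly reported hosts had 16 of 31 lower and 4 higher (16 and 4 over the list alone; 0.04169), as TULP4 (-2.57) and XPO1 (-2.25), but their median of -0.72 was -0.03 with RLE and 0.08 with total counts. With an estimated correlation only cell cycle passed (adjusted p = 0.001935). Fibroblast had 0.0649, macrophage 0.06737, lung 0.1569 and reported hosts 0.2282. With total counts the lung (adjusted p = 0.0917) and reported host (0.682) calls were lost. Not passing were lymphocyte (4 higher, 2 lower of 7; 5 and 2 over the list alone; 0.0986), astrocyte (3 and 1 of 10; 0.0807), endothelial (2 of 5 higher; 0.14), epithelial (2 of 4 higher; 0.285), ion channels (3 and 3 of 21; 0.399), presynaptic (4 of 20 lower, 3 over the list alone; 0.88), postsynaptic (1 and 2 of 20; 0.771), oligodendrocyte (3 and 1 of 12; 0.256), ribosomal (1 of 5 higher; 0.645) and long transcripts (2 of 8 higher, MALAT1 log2 2.92; 0.131). Neutrophil (1 of 2) and platelet genes (1 of 1) had 1 higher and erythroid genes 0 of 2. The ribosomal and erythroid medians (-0.24 and -0.52) turned positive with both other scalings.

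Against brain, tumour circles were again higher for LYZ (log2 10.45), CYBB (9.44), PIK3AP1 (at least 1228-fold), COL3A1 (at least 479-fold), COL1A2 (1374-fold, interval 468 to 6684), FYB1 (921-fold, 252 to 7643) and ABCA1 (7.48). The iron exporter SLC40A1 (2217 ± 141 against 14.8 ± 0.786 CPM, 7.22), the aminotransferase BCAT1 (7.45) and the semaphorin SEMA5A (7.07) were higher as well. Of the tumour reads of these 3, 0%, 0.269% and 22.6% lay on exon ends. Brain genes were at 0 in the tumour: NTRK2 (1113-fold), KCNN2 (539.7-fold), DGKB (502-fold), FMN2 (390.5-fold), SLC4A10 (366-fold), NDST3 (359-fold), LRP1B (351.5-fold), SLC1A2 (283-fold), SLAIN1 (264-fold) and SLC9C2 (248-fold), each fold a lower bound. With edgeR 1213 of 6669 host genes were higher and 2586 lower. Higher calls made up 31.9% with TMM, 43.5% with RLE and 49.9% with total counts. The median of all host genes was -1.31, -0.72 and -0.43, and list values below are to be read against it.

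Lists lower in tumour than brain were presynaptic (18 of 20, 18 over the list alone; camera adjusted p = 4.203e-07; median -8.41, -5.62 at the bound), as CADPS2 (log2 -5.81), postsynaptic (19 of 20, 19 over the list alone; 0.0004631; median -7.95, -3.19 at the bound), as HOMER1 (-5.85), and ion channels (16 lower, 1 higher of 21, 17 and 1 over the list alone; 0.002688; median -7.01, -2.66 at the bound), as NALCN (-7.01). Astrocyte genes (6 lower, 1 higher of 10, same over the list alone; 0.04126; median -3.30, -1.92 at the bound) and commonly reported hosts (20 lower, 4 higher of 31, 21 and 4 over the list alone; 0.01472; median -1.36, close to that of all genes), as PTK2 (-3.10), were lower too. Fibroblast genes (7 higher, 2 lower of 13, 8 and 2 over the list alone; 3.583e-05; median 4.19), as FN1 (5.66) and SPARC (5.37), macrophage genes (5 higher, 1 lower of 7, same over the list alone; 0.0002435; median 3.88), as MRC1 (4.63), and lymphocyte genes (4 higher, 1 lower of 7, 5 and 1 over the list alone; 0.02477; median 2.67), as PTPRC (4.56), were higher. None of these 8 calls held with an estimated correlation, where adjusted p ran from 0.0649 for fibroblast and macrophage, 0.077 for presynaptic, 0.1569 for postsynaptic, 0.17 for reported hosts, 0.1944 for lymphocyte and 0.2282 for astrocyte to 0.2954 for ion channels. With total counts the astrocyte (adjusted p = 0.076) and reported host (0.3025) calls were lost. Not passing were cell cycle (9 higher, 7 lower of 26; 0.261), epithelial (3 of 4 higher; 0.0659), oligodendrocyte (7 of 12 lower; 0.14), lung (2 of 3 higher; 0.338), endothelial (1 and 1 of 5; 0.524), ribosomal (1 of 5 higher; 0.345) and long transcripts (3 and 2 of 8, NEAT1 4.29 and MALAT1 2.52; 0.0659). Neutrophil (2 of 2), erythroid (1 of 2) and platelet genes (1 of 1) were higher. The endothelial median (-0.83) was 0.01 with total counts, and for cell cycle and endothelial genes the sign of the median differed from that of the test.

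**Figure D3:**
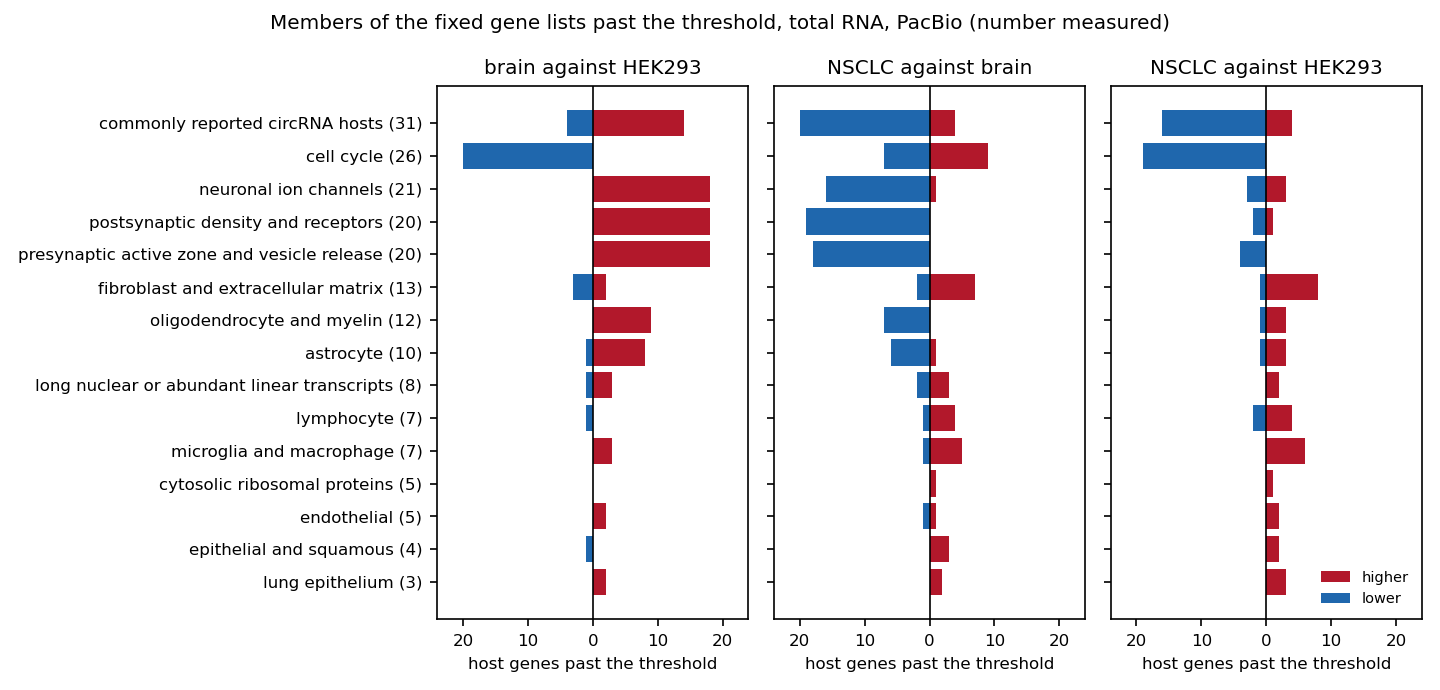
Number of genes of each list (y axis, number measured in brackets) that passed the edgeR threshold as higher (red, to the right) or lower (blue, to the left) in 3 comparisons of total RNA on PacBio. Of 26 cell cycle genes 20 were lower in brain and 19 lower in NSCLC than in HEK293.

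Many tumour calls rested on circles off annotated exon ends. Among the 1213 host genes higher than in brain, 717 had no read on exon ends, and the median share of reads there was 0%. Among the 2586 genes higher in brain the median was 97.7%. Counted from exon-end circles only, a choice made after seeing the data, fibroblast genes were no longer called (2 higher, 1 lower of 5; camera adjusted p = 0.758 against brain, 0.423 against HEK293). Macrophage genes kept the call against HEK293 (3 of 5 higher; 0.0497) and lost it against brain (0.076), lymphocyte genes kept it against brain (4 of 6 higher; 0.0272), and reported hosts lost both (0.626 and 0.977). The presynaptic (6.067e-08), postsynaptic (0.0264) and ion channel (0.0142) calls against brain and the cell cycle call against HEK293 (6.141e-07) held. The astrocyte call against brain was lost (3 lower, 0 higher of 6; camera adjusted p = 0.155), and cell cycle genes were called higher against brain (7 higher, 1 lower of 24; 0.0497). Lung epithelium had 1 member measured and was not tested. These recounts were tested with the preset correlation only, not with an estimated one.

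Over all circles, 37.8 ± 1.63% of tumour reads lay on exon ends, against 76.3 ± 1.42% in brain and 63.5 ± 1.20% in HEK293 total RNA on PacBio. Reads inside exons made up 21.1 ± 0.613%, inside introns 27.6 ± 0.915% and intergenic 6.52 ± 0.156% in the tumour, against 8.18%, 7.36% and 1.47% in brain and 10.1%, 16.8% and 1.47% in HEK293. Isoforms of 2 or more exons took 32.6 ± 0.526% of tumour reads (81.4 ± 1.64% in brain, 60.3 ± 0.98% in HEK293). With 3 libraries against 3, no exact test of these shares can go below p = 0.1. The 3 tumour libraries shared few circRNA levels: Pearson's r of log2 levels across circRNAs with at least 20 counts in a pair of libraries was 0.0188, -0.214 and 0.00612, against 0.589 to 0.87 in the other groups (circRNAs are not independent replicates).

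**Figure D4:**
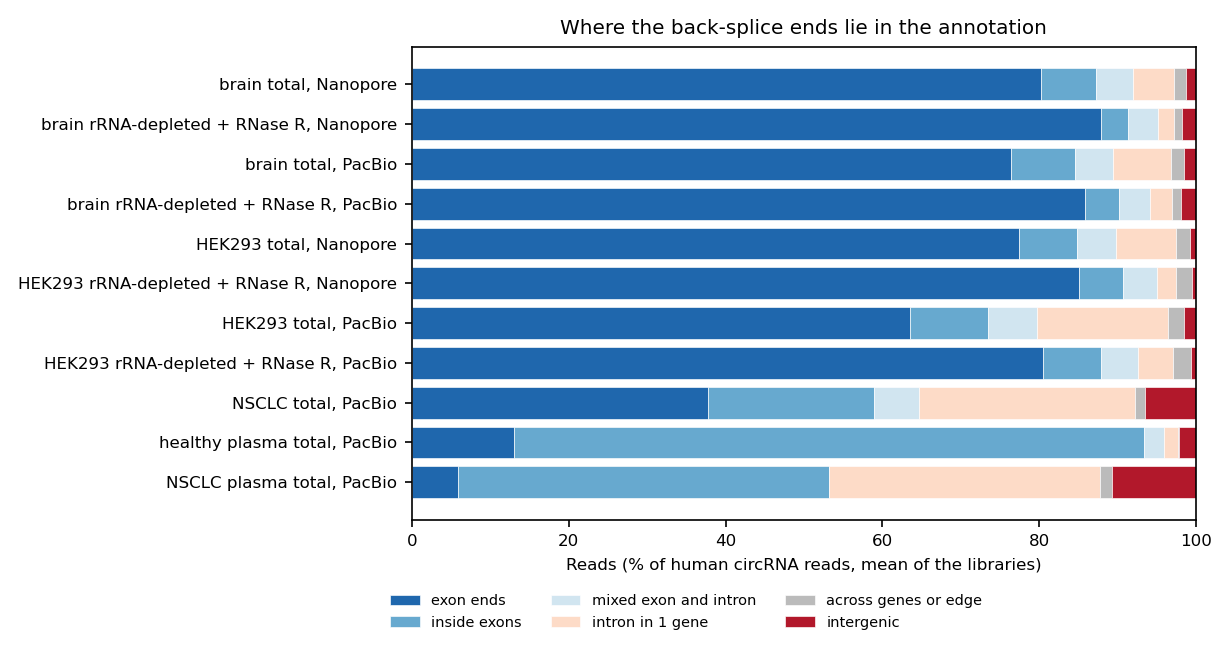
Mean percent of human circRNA reads (x axis, stacked bars) by position class in each group (y axis). Exon ends, the leftmost segment, hold 37.8% in NSCLC tumour, 76.3% in brain and 63.5% in HEK293 total RNA on PacBio.

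Among single circRNAs the tumour was highest over HEK293 for SCN7A (944 nt, chromosome 2, 166447612 to 166472445, 1610 ± 289 CPM, at least 692-fold), an intergenic circle on chromosome X, 94525211 to 94529483 (at least 154-fold), RGS22 (at least 152-fold), PAPOLA, a poly(A) polymerase (inside exons, at least 124-fold), and 1 in exons assigned to both CAP1 and PPT1 (at least 121-fold). It was lowest for AC127502.1 (at least 205-fold), ATRNL1 (536 and 799 nt, at least 153-fold and 199-fold), HNRNPU and SUCO. Over brain it was highest for the cyclin gene CCNI (874 nt inside exons, 1004 ± 136 CPM, at least 1341-fold), the same circle on chromosome X (at least 479.5-fold), PAPOLA (at least 385-fold), MALAT1 (at least 365-fold) and the p53 regulator MDM2 (4203 nt on exon ends, at least 346-fold), and lowest for 4 circles of ATRNL1 (11175 ± 985 CPM to 0 for the most read, at least 2120.0-fold) and NTRK2 (371 nt, at least 615.5-fold). With edgeR 1579 of 35978 circRNAs were higher and 11325 lower than in brain, and 781 higher and 2854 lower than in HEK293. Against brain 7486 and 7849 were called without NSCLC replicates 1 and 3, 21277 without brain replicate 1 and 6434 when only these groups were fitted. Against HEK293 there were 1847 and 1925 without NSCLC replicates 1 and 3, 2354 and 2176 without HEK293 replicates 1 and 2, and 2302 with only these groups. The higher share of calls was 12.2% against brain (31.8% with RLE, median shift 0.36, and 41.2% with total counts) and 21.5% against HEK293 (40.0% with total counts). Of 3492 circRNAs in all 3 tumour libraries, 94.9% were also seen in brain and 91.5% in HEK293. These were a small part of the 26119 to 54376 circRNAs of each tumour library. In the other direction, 27.5% of 39343 brain and 56.7% of 13110 HEK293 circRNAs were seen in the tumour. Such shares depend on the depth of the libraries searched, which in human reads was lowest in the tumour.

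PacBio and Nanopore read largely the same circRNAs. Of the circRNAs in all 3 libraries of a Nanopore group 99.8% to 99.9% were seen with PacBio, and of those in all 3 PacBio libraries 85.4% (brain total), 78.4% (brain treated), 62.2% (HEK293 total) and 77.2% (HEK293 treated) were seen with Nanopore. Nanopore libraries held fewer reads than PacBio libraries of the same tissue and preparation, and the share seen depends on depth. PacBio gave a median length longer by 112 nt (187 nt when each circRNA counted once) and 6.41 points more reads in circles of 1000 nt or longer, while the share in isoforms of 2 or more exons fell by 4.16 points (exact permutation, adjusted p = 8.75e-05 for each of the 3). Reads on exon ends fell by 6.10 points (exact permutation, adjusted p = 4.375e-05), each in 4 of 4 strata. When each circRNA counted once the differences of the last 2 shares were -18.9 and -22.2 points. With same-numbered libraries swapped within pairs these 4 have adjusted p = 0.000684 (exact permutation, from the smallest p that 4096 arrangements can give). The share of the 10 most abundant fell by 0.693 points (exact permutation, adjusted p = 0.0377, 3 of 4 strata) but did not pass without replicate 1, 2 or 3 in every group (0.167, 0.0504 and 0.119), and the mitochondrial share did not pass (0.86). The edgeR test called 3375 of 16597 circRNAs higher with PacBio and 29 lower (2193 to 4919 calls with 1 library left out). Among the platform calls 99.1% were higher with TMM, 31.03% with RLE (58 called) and 13.5% with total counts (104 called), so no direction holds across scalings. The only circRNA that met the naming rule was 1 of ZNF680 (348 nt, chromosome 7, 64543707 to 64544432), lower with PacBio (0.091 against 128.5 CPM, 1189-fold, 328 to 9842).

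The exon blocks read within a circle also differed between brain and HEK293. In the circle of the arginyl-tRNA synthetase RARS (chromosome 5, 168488602 to 168494650), the 534-nt isoform held 81.0 ± 3.03% of reads in brain and 57.2 ± 7.70% in HEK293, and the remainder went to a 2043-nt isoform in brain and a 2127-nt isoform in HEK293 (adjusted p = 8.089e-05 by edgeR). In INTU, a planar polarity gene, a 477-nt isoform held 88.9 ± 1.99% in brain and 0 in HEK293, where a 638-nt isoform held 49.7 ± 6.09%. In MINDY3, a deubiquitinase, a 2021-nt isoform held 94.0 ± 1.87% in brain and 0 in HEK293, where isoforms of 636 and 4691 nt held 49.4% and 50.6%. In FAM135A an 872-nt isoform (99.3 ± 0.442%) stood against a 950-nt isoform in HEK293 (90.6 ± 1.33%), and in the helicase gene HFM1 a 1191-nt isoform (99.7 ± 0.580%) against 1 of 1271 nt (98.1 ± 1.03%). In INTU and FAM135A the isoforms named differed by a whole exon block. In RARS, MINDY3 and HFM1 they differed by blocks that were longer or joined across the gap between them. Of 4764 circRNAs with 10988 isoforms tested by edgeR diffSpliceDGE, 202 passed (795 at unadjusted p under 0.05). Leaving out 1 library gave 112 to 153, and a gene-level F test 1034. With the replicate number as a block 0 passed, and all 5 named circles lost their call. Replicate numbers are not taken to pair the samples, but the number of calls depends on the libraries and the test.

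The plasma libraries, with no replicates, held few circRNAs. Healthy plasma had 291 circRNAs, and 79.6% of its reads came from 1 circle of 124 nt in the mitochondrial ribosomal RNA gene MT-RNR2 (chromosome M, 2625 to 2748, 35535 counts). Next were host genes SAFB, a chromatin-binding protein (1658 counts), CARNMT1, a methyltransferase (582), AGTPBP1, a deglutamylase (289), and the phosphatase CDC14B (276), all at 0 in NSCLC plasma (lower bounds of 228-, 80.0-, 39.7- and 37.9-fold, and 4883-fold for MT-RNR2). NSCLC plasma had 187 circRNAs, and 46.4% of its reads came from a 1693-nt circle inside exons of TAL1, a blood-forming transcription factor (chromosome 1, 47217263 to 47218955, 8541 counts, at least 6908-fold over healthy plasma). The matrix gene LTBP1 (813 counts, at least 658-fold), the kinase MAP3K5 (69, at least 55.8-fold), the transcription regulator AFF1 (43, at least 34.8-fold) and the erythroid ankyrin ANK1 (38, at least 30.7-fold) were at 0 in healthy plasma, and the splicing factor MBNL1 had 41 and 26 counts (ratio 3.83, 2.29 to 6.51). An intronic circle on chromosome 2, 49046950 to 49057636, held 31.8% of NSCLC plasma reads. All these folds are relative to all reads of a library, and 35550 of the 44625 healthy plasma reads were mitochondrial. Without these, healthy plasma held 9075 reads and NSCLC plasma 18392. On that base every fold of NSCLC over healthy plasma is several times smaller, and MBNL1 is no longer higher in NSCLC plasma. Those of SAFB, CARNMT1, AGTPBP1 and CDC14B in healthy plasma are larger.

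No mitochondrial read was seen in NSCLC plasma (0 of 18392, 95% interval up to 0.0201%), against 79.7% in healthy plasma (79.3 to 80.0%). Exon-end circles made up 48.8% of healthy plasma circRNAs (42.9 to 54.7%) and 11.8% of NSCLC plasma circRNAs (7.52 to 17.3%), and intergenic ones 23.0% and 44.9%. In healthy plasma 32.0% (26.6 to 37.7%) of circRNAs were also seen in the NSCLC tumour, 44.3% in brain and 35.7% in HEK293. In NSCLC plasma these were 6.42% (3.36 to 10.9%), 9.09% and 7.49%. The order follows the size of the sets searched, which were total RNA on PacBio. Tumour libraries held 26119 to 54376 circRNAs each, brain 132592 to 197311 and HEK293 64274 to 87837. These shares therefore do not show which tissue the plasma circles resemble. Of the gene lists, healthy plasma had counts for mitochondrially encoded genes (35548), commonly reported hosts (89 in 5 members), lymphocyte (BANK1, 82), macrophage (LYN, 10) and long transcripts (MALAT1, 7). NSCLC plasma had counts for fibroblast (LTBP1, 813), erythroid (ANK1, 38), reported hosts (9 in 3 members) and platelet genes (ITGB1, 2). All other lists had 0 counts in both. With 1 library per group these values describe the 2 libraries only.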

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

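In this part the tests of ribosomal RNA removal, TMM scaling, low counts, genomic DNA, a few abundant NSCLC circRNAs and other groupings of the libraries were chosen only after the result was seen, whereas the tests of linear RNA and of a few abundant long circRNAs were written before.

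The effect of ribosomal RNA removal with RNase R differed between brain and HEK293 for 7186 circRNAs by a test of the difference itself, an edgeR interaction. Among 100 groupings of the same 12 libraries, the real one and others drawn at random by shuffling the 4 group labels, 5 gave a count as large, the real one included, and the highest other count was 19400. Such shuffles mix libraries of different tissue and treatment, so they carry those large differences and point to the structure of the samples. The number of calls is therefore not shown to lie beyond it.

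In the NSCLC libraries, 54.5% of all reads (SD 0.937, 3 libraries) lay on 6 spike-in contigs outside the main measurement, well above the limit that a count of 0 allows. By contig length they held 24.75% (403 bp), 39.9% (703 bp), 14.9% (1203 bp), 5.58% (1703 bp), 3.19% (1953 bp) and 11.7% (2703 bp) of the spike-in reads.

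After ribosomal RNA removal with RNase R the share of reads in circRNAs of 1000 nt or longer fell by 46.8 percentage points. Linear RNA read as circles in total RNA is argued against as the whole cause, because among reads on annotated exon ends the difference was -44.4 points. The 10 most abundant circRNAs of a total RNA library held 4.95 to 12.3% of its reads, far less than the fall. These shares argue against a few abundant long circRNAs as the whole cause. Leaving out the 10 most abundant of each tissue could therefore hardly change the difference. Its value without them, -45.6 points, adds no further evidence. RNase R and ribosomal RNA removal cannot be told apart, because 0 libraries had only 1 of the 2 steps. Loss of long circles through nicking by the treatment stays open and was not tested, and no biological explanation was tested.

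Of the circRNAs called between platforms, 99.1% were higher with PacBio. TMM scaling of libraries of different composition fits, since with total counts 13.5% of the calls were higher with PacBio. Low counts near the minimum of the circRNA caller cannot be told apart from scaling, because the 98.0% of calls higher with PacBio among circRNAs with a mean log2 CPM of 5 or more rest on the same TMM scaling. Of 100 groupings, with platforms shuffled at random within tissue and preparation, only 1, the real one with 3404 calls, gave a count as large, and the highest other gave 887, or 24 when platforms were swapped within same-numbered pairs. No biological explanation was tested, because both platforms read the same tissues.

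NSCLC tumour libraries had a lower share of reads on exon ends (37.8%) than brain (76.3%) or HEK293 (63.5%) total RNA. CircRNAs inside exons were 0.706 to 0.740 times as many as those inside introns in NSCLC, against 0.0283 for random places in the genome. In total RNA on PacBio, brain (0.533 to 0.592) and HEK293 (0.421 to 0.433) also lay far above random places, so that distance alone decides little. The ratio of intergenic to intronic circRNAs was 0.182 to 0.211 in NSCLC. It was nearer the random 0.904 than in the same brain (0.117 to 0.123) or HEK293 (0.081 to 0.0838) libraries. Genomic DNA would lower the first ratio, which among total RNA on PacBio was highest in the tumour. Treated brain and HEK293 libraries on PacBio lay higher still (0.840 to 0.972). Against total RNA on the same platform, genomic DNA is argued against as the whole cause, but not as a part. A few abundant circRNAs are argued against as the whole cause too, because the gap between the highest NSCLC and the lowest other library, 22.6 points by reads, shrank to 8.04 points but did not close when each circRNA counted once. Linear RNA read as circles cannot be told apart from a tumour property: reads inside exons fell by 2.91 points with RNase R in brain and HEK293, but no NSCLC library was treated. The biological explanation, another set of circles in tumour tissue, stays open, because tissue and library set are the same groups here.

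For the other comparisons only 10 groupings of the libraries exist, too few for a share under 0.05. The real grouping was the only 1 to reach its count in each. The real and the highest other counts of circRNAs were 20883 and 1 (RNase R, brain, PacBio), 15072 and 0 (RNase R, HEK293, PacBio), 7085 and 0 (RNase R, brain, Nanopore), 5456 and 0 (RNase R, HEK293, Nanopore), 19170 and 0 (brain against HEK293, PacBio), 6898 and 0 (the same, Nanopore), 12904 and 0 (NSCLC against brain) and 3635 and 0 (NSCLC against HEK293). For host genes they were 3618 and 0 (brain against HEK293), 3799 and 0 (NSCLC against brain) and 2430 and 1 (NSCLC against HEK293), and for isoform usage 202 and 0.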

How the results depend on the processing

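In this part the restriction to circRNAs with a mean log2 CPM of 5 or more, that to exon-end circles for gene lists, and the permutation with same-numbered libraries of both platforms moved together were chosen only after the data were seen. Each value below is a number of calls with the percent higher in brackets where it moved, and the cause was not tested except where fewer libraries or circRNAs entered by construction. Of the alternatives of the main answers, 344 stayed the same, 67 moved and 5 became weaker. Of 1339 alternatives for named circRNAs 1325 stayed the same and 14 became weaker, and of 2948 for named host genes 2851 stayed, 24 became stronger, 67 weaker and 6 reversed.

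With RLE in edgeR the calls were 7206 (31.8%) for NSCLC against brain, 58 (31.03%) for PacBio against Nanopore, 2961 (46.3%) for RNase R in HEK293 on Nanopore and 2612 (68.7%) for the interaction. With DESeq2 they were 7298 (32.1%), 327 (31.2%) and 2890 (41.2%) for the first 3 of these and 4556 (64.6%) for brain against HEK293 on Nanopore. With total counts they were 6210 (41.2%) for NSCLC against brain, 104 (13.5%) for PacBio against Nanopore and 4479 (60.2%) for brain against HEK293 on Nanopore. DESeq2 gave 73.6% higher in the interaction, 66.9% for RNase R in brain and 43.9% in HEK293 on PacBio, 59.0% for brain on Nanopore, 55.1% for brain against HEK293 on PacBio, and 44.4% and 54.9% of host genes for NSCLC against brain and HEK293.

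With only the groups of the contrast in the fit, the calls were 2302 (NSCLC against HEK293), 6434 (NSCLC against brain), 2716 (RNase R, HEK293, Nanopore), 3385 (brain against HEK293, Nanopore), 10200 (the same, PacBio), 13222 (interaction) and 1511 host genes (NSCLC against HEK293). Requiring 3 or more counts gave 1487 (platform), 7558 (RNase R, HEK293, PacBio), 15089 (RNase R, brain, Nanopore), 11179 (RNase R, brain, PacBio) and 9586 (brain against HEK293, PacBio). Among circRNAs with a mean log2 CPM of 5 or more there were 1890 (NSCLC against HEK293), 3518 (NSCLC against brain), 2047 (platform), 3162 and 4386 (RNase R, HEK293 and brain, PacBio), 4068 (brain against HEK293, PacBio) and 1998 (interaction). Counting only exon-end circles gave 1336 host genes for NSCLC against HEK293 and 2166 against brain.

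Gene lists past the threshold fell from 5 to 1 for NSCLC against HEK293, from 8 to 0 for NSCLC against brain and from 6 to 1 for brain against HEK293 with an estimated correlation. Total counts gave 3 lists for NSCLC against HEK293, without lung epithelium and reported hosts, and 6 against brain, without astrocyte and reported hosts. From exon-end circles there were 2 (NSCLC against HEK293), 5 (NSCLC against brain) and 1 (RNase R in HEK293, from 0, cell cycle genes lower).

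Leaving out 1 library gave 1847 to 4238 calls for NSCLC against HEK293 (1847 and 1925 without NSCLC replicates 1 and 3, 2354 and 2176 without HEK293 replicates 1 and 2) and 7486 to 21277 for NSCLC against brain (7486 and 7849 without NSCLC replicates 1 and 3, 21277 without brain replicate 1). The range was 2193 to 4919 for the platforms (2193 without treated brain Nanopore replicate 2), 2991 to 5491 for RNase R in HEK293 and 4118 to 7365 for brain against HEK293 on Nanopore, both lowest without HEK293 total replicate 2. The interaction gave 5117 to 13881, moving for treated HEK293 replicates 1 to 3 (12363, 11665, 11813), HEK293 total replicate 3 (12254), treated brain replicates 1 and 3 (12465, 12073) and brain total replicates 1 and 2 (13881, 11458). Isoform usage gave 112 to 153 (121 and 134 without HEK293 replicates 2 and 3, 113 and 112 without brain replicates 2 and 3). For library measures the same replicate number was left out of all 8 brain and HEK293 groups at once. There the share of the 10 most abundant between platforms ran from -0.733 to -0.644 points and no longer passed (exact permutation, adjusted p = 0.167, 0.0504 and 0.119), and the mitochondrial share of brain over HEK293 from 0.000144 to 0.000177 points (0.117 without replicate 3). The other counts of circRNAs and host genes stayed within 1.5 times, and no other measure lost or gained a call. The gene lists were not run with libraries left out.

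Within a platform, libraries with the same replicate number did not deviate together (r across circRNAs under 0.1), so the numbers are not taken to pair the samples. With the number as a replicate block 0 circRNAs passed for isoform usage and 3232 for the platforms, and no other answer moved. Across platforms every library correlated best with its own number in all 4 comparisons, a hint from the data only. With these moved together in the permutation no measure lost or gained a call. The gene-level F test of isoform usage gave 1034 calls.

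When each circRNA counted once, the exon-end share of brain over HEK293 was 0.926 points (exact permutation, adjusted p = 0.507). Leaving out mitochondrial circRNAs in healthy plasma, the 10 most abundant held 53.9% of reads, exon-end circles 64.3%, intergenic 10.6% and intronic 9.06%.

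From exon-end circles alone, PLXDC2 reversed to -4.75 (adjusted p = 0.664 by edgeR) against HEK293 and -8.24 (0.0352) against brain, PTPRB to -4.72 (0.638) against HEK293 and EEF1A1 to -2.53 (0.774) against brain in NSCLC, and FN1 to 1.48 (0.505) for brain against HEK293. With total counts STXBP5 reversed to 0.061 (adjusted p = 1 by edgeR) for NSCLC against HEK293. The cause was not tested.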

Other observations

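In this part no hypothesis was tested; the values were looked at only after the main results were seen.

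Among circRNAs with an isoform of at least 10 reads, the share with 2 or more such isoforms was, over the groups of 3 libraries, lowest in NSCLC tumour (2.68%, 313 of 11702) and highest in HEK293 total RNA on PacBio (9.58%, 1189 of 12410). It was 7.23% in brain total RNA on PacBio, 27.3% (12 of 44) in the single NSCLC plasma library and 5.26% (5 of 95) in the healthy one, and the largest number of isoforms of a circRNA was 8.

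After ribosomal RNA removal with RNase R, 48.3% of the 43580 circRNAs present in all 3 HEK293 PacBio libraries were also seen in total RNA, against 78.0% of 38592 in brain. In the other direction, 83.5% of HEK293 and 70.8% of brain circRNAs of total RNA were seen after the treatment. The share seen depends on the depth of the libraries searched. HEK293 total libraries held 455442 to 639870 reads and treated ones 2414091 to 2636273. In brain these were 1762301 to 2933800 and 2473411 to 3386583. Tissue and depth therefore cannot be told apart here.

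The dispersion index of replicate libraries, 1 under counting noise alone, ran from 1.36 to 18.5. It was 12.8 to 18.5 for the 3 NSCLC tumour pairs and 5.66 to 16.05 for the 6 brain PacBio pairs.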
